A study of Ceratopteris richardii with 15 samples.

How the data were processed

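RNA was measured in 15 libraries from sporophytes of the fern Ceratopteris richardii, wild type RNWT1, at 50 days. There were 5 tissues with 3 libraries each: root tip, root without its tip, leaf tip, leaf without its tip, and shoot tip. Root and leaf stand below for the organs without their tips. Per the labels' protocols, total RNA was extracted with TRIzol and libraries were made with standard Illumina methods. The values were deposited as 1 table of TPM (transcript abundance scaled by gene length and to a fixed total in each library) for 88641 genes. The submitters' processing notes name Trim Galore 0.5.0, Bowtie2 2.3.4.3 and RSEM 1.3.2, without giving their settings. The deposited TPM values have 2 decimals and sum to 1000000 in each library up to rounding, so the sequencing depth is unknown and no counting interval or detection floor could be given. An exact 0 in such a table can be a failed estimate as well as a low level. Such genes are therefore described as listed at 0.

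The gene identifiers have the form that the Trinity assembler writes, with a prefix that matches the tissue codes of the columns. The table pairs them with no name or description. A reference table with 36816 genes of the assembly GCA_020310875.1 was searched, and 0 identifiers matched. Genes are therefore given by identifier, with no position, no annotation and no statement of function. For the same reason the tests of gene lists that had been planned for pathways and cell types were not run. Genes assembled separately from related copies, or 1 gene split over several identifiers, were not resolved here, and reads shared between close copies make single values uncertain.

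Columns were joined to libraries through the sample descriptions. The 3 leaf columns have names that match the leaf group and no single leaf sample, so these libraries are called leaf replicate a, b and c and were given no replicate number. No label says that replicates came from separate plants or cultures. The p-values therefore measure only the spread between these samples, which may be technical.

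Genes with at least 1 TPM in 3 or more libraries were tested (39490 genes). Values were analysed as log2(TPM + 1) with limma 3.58.1 in R 4.3.3, using empirical Bayes moderation with an intensity trend and 1 mean per tissue. All 15 libraries entered a single fit with 10 residual degrees of freedom. The pseudocount of 1 makes the log2 fold changes of low genes understate their change. A gene was called in a pairwise comparison when the Benjamini-Hochberg adjusted p was under 0.05 and the absolute log2 fold change was at least 1, which is 2-fold. All adjusted p-values come from this procedure. A moderated F test over the 5 tissues used the adjusted p alone. A gene was counted as enriched in a tissue when it was called higher there than in each of the other 4 tissues. The difference of the tip effect between organs was tested as an interaction contrast, root tip minus root against leaf tip minus leaf. The number of genes shared by lists of calls was set beside the number that independent lists of the same sizes would share. Principal components and correlations were computed on log2(TPM + 1) of the tested genes. Errors after a ± sign are standard deviations between libraries, and SE is the standard error of a fitted log2 fold change. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

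The genes named in the text follow a rule fixed before the data were examined. For 5 of the pairwise comparisons it takes the 2 genes with the largest and the 2 with the lowest log2 fold change among the called genes. These genes need a mean of at least 10 TPM in the higher tissue and replicates of the 2 tissues that do not overlap. For each tissue the enriched gene with the largest smallest difference to the other tissues is added. No gene was named for the comparison of root tip with leaf tip.

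The fit was tested on simulated data over 39490 genes with known changes between root tip and root. The changed genes were drawn only from those with a mean of at least 2 TPM, averaged on the log2 scale. Recovery of lower genes was not tested, and no counting noise was simulated. Few genes were changed, with directions balanced, and noise was drawn from the fitted spread. The simulated values were not rescaled to a fixed total, so false calls that come from scaling were not tested. Of 50 genes changed 3-fold, 45 were called in the right direction, as were 50 of 50 changed 6-fold and 49 of 50 changed 12-fold. None of the 50 genes changed 1.5-fold passed the 2-fold minimum, for a count of 0. There was 1 false call among 39290 unchanged genes. For root tip enriched genes, 50 of 50 simulated genes raised 6-fold or 12-fold were found with 0 false calls. The interaction contrast found 94 of 100 and made 2 false calls.

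Alternatives tried were pseudocounts of 0.1 and 5, no filter, a mean of at least 5 TPM, median-ratio scaling, quantile normalization, array quality weights, no intensity trend, a replicate block, a fit to only the tissues compared, and each library left out in turn. Averaging root replicates 1 and 2 and leaving out root-only genes were added after the data were seen. Root-only genes are those with a root mean of at least 0.3 TPM whose level in every library of the other 4 tissues is under 10% of the root mean. For the genes that differ from both root and leaf in all 3 tips, libraries with unchanged tips were simulated in 10 draws from the fitted means and residual spread, with each tip set to the higher (or, for genes lower in the tips, the lower) of the root and leaf means.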

Results

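The transcriptome of Ceratopteris richardii, a homosporous fern used as a laboratory model, was compared between the growing tips of its organs and the older parts behind them. Fern roots, leaves and shoots grow from apical cells at their tips. The design separated root tip from the rest of the root, and leaf tip from the rest of the leaf, and it added the shoot tip. Each tissue of the 50 day sporophytes had 3 libraries. The number of genes at 1 TPM or more was 30045 ± 32.6 in root tip, 34055 ± 1670 in root, 32238 ± 204 in leaf tip, 27398 ± 249 in leaf and 33758 ± 300 in shoot tip (SD, n = 3 each). Expression was concentrated in fewer genes in leaf and root than in the tips. The 10 most abundant genes held 13.8% ± 0.45 of the summed TPM in leaf and 8.86% ± 0.68 in root, against 4.48% ± 0.026 in root tip, 4.36% ± 0.017 in leaf tip and 4.13% ± 0.18 in shoot tip (SD, n = 3 each).

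The 5 tissues separated from each other, and the nearest pair was leaf tip and shoot tip. Across genes, the tissue means on the log2 scale correlated with r = 0.95 between leaf tip and shoot tip and r = 0.866 between root tip and shoot tip. Each tip was less similar to the organ behind it, with r = 0.788 for root tip and root and r = 0.784 for leaf tip and leaf. The lowest value was 0.599, between root and leaf tip. These correlations are across genes, which are not independent replicates. Between single libraries the correlation of leaf tip with shoot tip was 0.944 to 0.948, below the 0.99 to 0.995 found within root tip, leaf tip, leaf and shoot tip. The leading 3 principal components held 51.9%, 27.4% and 13% of the variance.

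**Figure D1:**
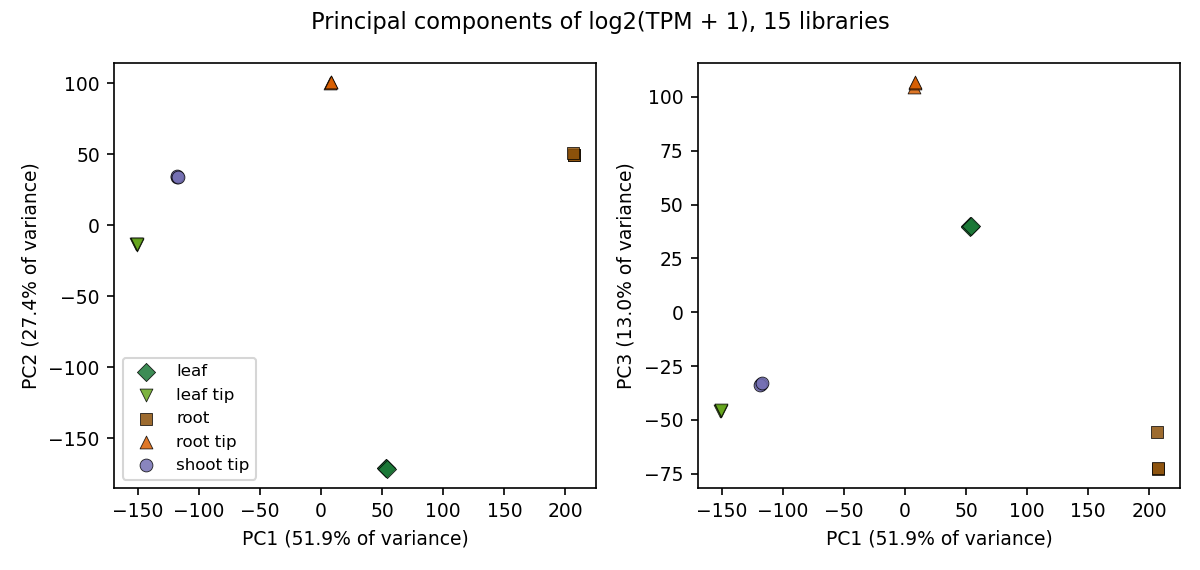
Principal components of log2(TPM + 1) over the tested genes, with component 1 on the x axis and component 2 (left) or 3 (right) on the y axis; each point is 1 of 15 libraries, coloured by tissue. Leaf tip and shoot tip lie close together on component 1, which holds 51.9% of the variance, and leaf stands apart on component 2, which holds 27.4%.

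Root replicate 3 stood apart from the other root libraries. Across genes it correlated with them down to r = 0.971, while root replicates 1 and 2 correlated at 0.993. Of 13321 genes at 10 TPM or more in root, not counting the root-only genes described next, 318 were more than 2-fold higher and 237 more than 2-fold lower in replicate 3 than in the other root libraries, against 10 that differed by over 2-fold between replicates 1 and 2. A set of 11526 genes, 13% of the table, was listed almost only in root: every library of the other tissues held under 10% of the root mean. Of these root-only genes 11460 carried the root prefix, 10270 were listed at 0 in all 12 other libraries, and 909 passed the filter for testing. They held 9.74% ± 0.54 of the summed TPM of the root libraries, of which 7.56% ± 0.61 lay in the 97 genes at 100 TPM or more (SD, n = 3). At 1 to 10 TPM, 22.8% of them were more than 2-fold higher and 62.3% more than 2-fold lower in replicate 3 than in replicates 1 and 2. For the 97 abundant genes these shares were 9.28% and 11.3%.

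**Figure D2:**
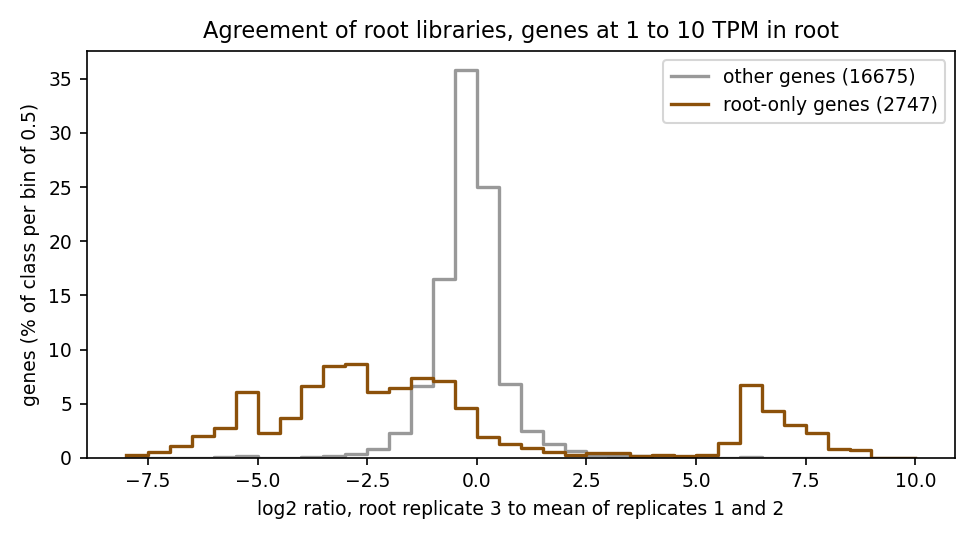
Distribution of the log2 ratio of root replicate 3 to the mean of root replicates 1 and 2 (x axis) for genes at 1 to 10 TPM in root, as percent of each class per bin (y axis), for root-only genes and for other genes. The interquartile width of the ratio was 3.8 for root-only genes and 0.716 for the others.

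Most genes differed among the tissue samples beyond the spread of replicates, which may be technical. At 100 TPM or more, the SD of the log2 ratio between 2 libraries was 0.0371 to 0.176 within root tip, leaf tip, leaf and shoot tip. In root it was 0.0639 between replicates 1 and 2, and 0.663 and 0.658 between these and replicate 3. By the moderated F test of limma, 37754 of 39490 tested genes (95.6%) passed, and 28331 (71.7%) of those tested also spanned at least a 2-fold range between tissue means. A majority were nonetheless present throughout the plant, with 21934 genes (55.5%) at a mean of 1 TPM or more in all 5 tissues. Another 4755 genes (12%) reached that level in 1 tissue only, of which 1787 did so in root, 931 in leaf tip, 921 in shoot tip, 561 in root tip and 555 in leaf.

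The comparison of root tip with root asked which genes distinguish the growing end of the root from the tissue behind it. In root tip 7412 genes were higher and 5162 were lower. The higher genes made up 38.2% ± 0.072 of the summed TPM in root tip and 10.5% ± 0.34 in root, and the lower genes 6.3% ± 0.018 in root tip and 36.4% ± 0.28 in root (SD, n = 3). LA_TRINITY_DN4088_c0_g1 averaged 2352 ± 15.6 TPM in root tip and 2.93 ± 2.27 in root (SD, n = 3; log2 fold change 9.37, SE 0.25, adjusted p = 2.8e-13). RO_TRINITY_DN13492_c0_g1 averaged 2660 ± 9.84 TPM in root tip and 3.64 ± 0.615 in root (log2 fold change 9.17, adjusted p = 9.2e-19). Both were also abundant in the other tips, at 3693 ± 12.2 and 1812 ± 12.6 TPM in leaf tip and 4353 ± 57.3 and 2597 ± 10.6 TPM in shoot tip. In the opposite direction, LE_TRINITY_DN43418_c0_g1 averaged 4672 ± 881 TPM in root and 1.03 ± 0.178 in root tip (log2 fold change -11.15, SE 0.16, adjusted p = 8.5e-16). It is one of the root-only genes, and its root replicate 3 was lower, at 3654.94 TPM against 5172.64 and 5187.51. RO_TRINITY_DN9043_c0_g1 averaged 1360 ± 118 TPM in root, 142.8 ± 2.27 in leaf and 0.647 ± 0.162 in root tip (root tip against root, log2 fold change -9.69, adjusted p = 1.8e-17). Of the 909 tested root-only genes, 908 were among those lower in root tip, which follows largely from their selection. The share of calls higher in root tip was 58.9% as deposited, 53.2% after median-ratio scaling and 51.2% after quantile normalization. Under all 3 scalings 6217 genes were higher and 5160 lower in root tip. With a pseudocount of 5 the 2 directions together fell from 12574 to 6644 genes, and with a mean of at least 5 TPM required they came to 7972.

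**Figure D3:**
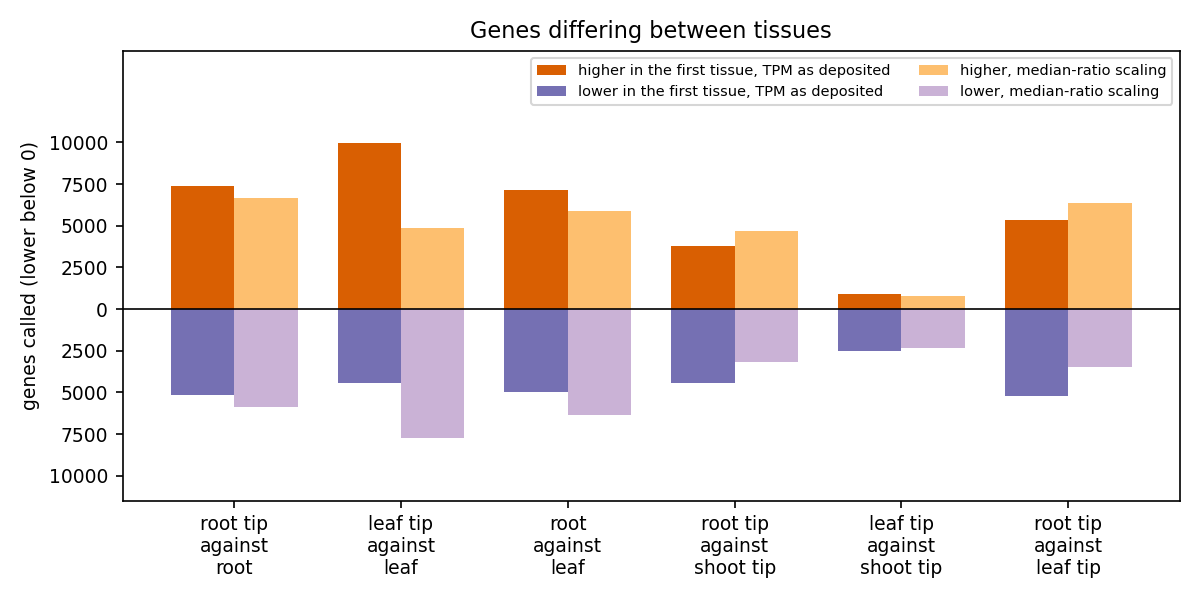
Number of genes called higher (above 0) or lower (below 0) in the tissue named first (y axis) for 6 pairwise comparisons (x axis); dark bars use TPM as deposited and pale bars median-ratio scaling. For leaf tip against leaf the counts were 9982 higher and 4422 lower as deposited, and 4840 higher and 7747 lower after median-ratio scaling.

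Leaf tip and leaf differed in 14404 genes. As deposited, 9982 genes were higher and 4422 lower in leaf tip. The higher genes held 45.6% ± 0.0074 of the summed TPM in leaf tip and 12% ± 0.13 in leaf, and the lower genes 10.2% ± 0.029 in leaf tip and 48.3% ± 0.45 in leaf (SD, n = 3). LE_TRINITY_DN5604_c0_g1 reached 4635 ± 6.08 TPM in leaf tip and 1.41 ± 0.41 in leaf (log2 fold change 10.92, SE 0.28, adjusted p = 1.9e-13), with 3486 ± 30.5 TPM in shoot tip and 68.2 ± 2.19 in root tip. RO_TRINITY_DN44984_c0_g1 averaged 1660 ± 25.3 TPM in leaf tip and 1.95 ± 0.402 in leaf (log2 fold change 9.15, adjusted p = 1.8e-14). LE_TRINITY_DN3074_c0_g1 averaged 2587 ± 15.5 TPM in leaf and under 1 TPM in each of the other tissues, with 0.253 ± 0.116 in leaf tip (log2 fold change -11.02, adjusted p = 1.1e-14). LE_TRINITY_DN2085_c0_g1 was at 1499.12, 1541.42 and 1541.79 TPM in the leaf libraries and listed at 0 in the 3 leaf tip libraries. The balance of directions depended on the scaling. Median-ratio scaling moved the median log2 difference of all genes by -0.41, and 38.5% of the calls were then higher in leaf tip, against 69.3% as deposited and 48.7% after quantile normalization. After quantile normalization 6052 genes were higher and 6385 lower in leaf tip, and 4797 were called higher and 4403 lower under all 3 scalings. With a pseudocount of 5 the 14404 calls as deposited became 7737.

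The tip effect was partly shared by root and leaf. Of the genes higher in root tip than root, 3993 were also higher in leaf tip than leaf, where independent lists of those sizes would share 1873.6. Likewise 1572 genes were lower in both tips, where independent lists would share 578. Genes with opposite calls were fewer than independent lists would give, with 509 higher in root tip and lower in leaf tip (830 for independent lists) and 256 in the reverse direction (1304.8). The log2 differences of the 2 comparisons, which share no library, correlated across genes with r = 0.448 and rho = 0.44. Median-ratio scaling changed the shared counts to 2482 higher and 2433 lower, and these were 3.04 and 2.12 times the numbers for independent lists. Without root-only genes 3993 genes were higher and 1506 lower in both. A pseudocount of 5 gave 1923 and 777 genes, and one of 0.1 gave 2486 genes lower in both tips.

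**Figure D4:**
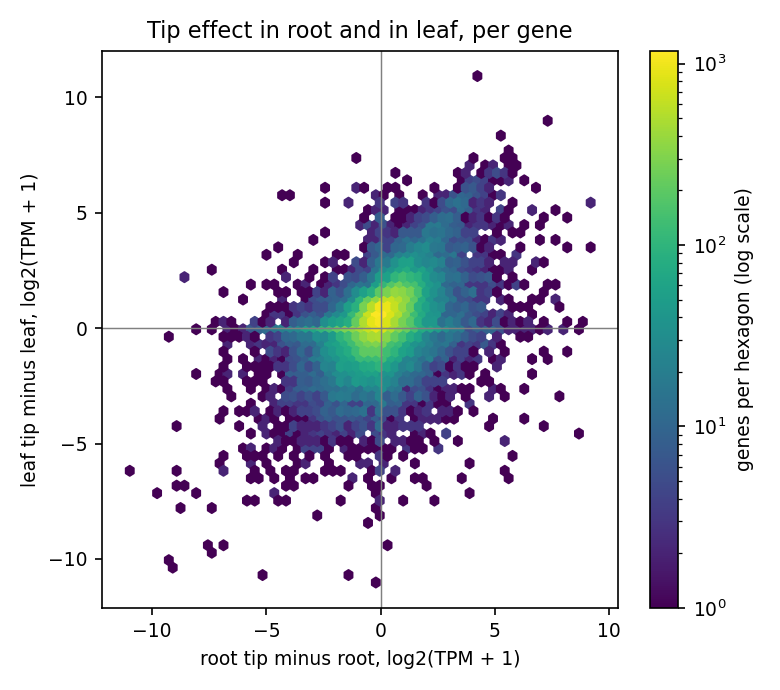
Difference of log2(TPM + 1) between root tip and root (x axis) and between leaf tip and leaf (y axis) for the 39490 tested genes, with colour for the number of genes per hexagon on a log scale. The differences correlated across genes with r = 0.448.

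The size of the tip effect also differed between root and leaf for 15125 genes by the interaction contrast, of which 5576 had the higher tip-minus-organ difference in root and 9549 in leaf. Among them 3334 genes were called higher in leaf tip with no call in root tip, and 1971 were called higher in root tip with no call in leaf tip. Another 2720 were lower in root tip alone and 1743 lower in leaf tip alone, 1900 were called in the same direction in both organs, 765 in opposite directions and 2692 in neither. LE_TRINITY_DN3074_c0_g1, which was abundant in leaf alone, had an interaction of 10.97. The share with the higher difference in root was 36.9% as deposited, 58.3% after median-ratio scaling, which moved the median interaction of all genes by 0.43, and 49.7% after quantile normalization. Median-ratio scaling gave 8424 genes with the higher difference in root and 6035 in leaf. Under all 3 scalings 5545 genes had the higher difference in root and 5753 in leaf. A pseudocount of 5 left 7227 genes, and a mean of at least 5 TPM left 7917.

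Root and leaf, the mature parts of the organs, differed in 12112 genes, of which 7154 were higher in root and 4958 higher in leaf. The root-higher genes held 42.9% ± 0.33 of the summed TPM in root and 8.03% ± 0.029 in leaf, and the leaf-higher genes 49.6% ± 0.42 in leaf and 6.63% ± 0.24 in root (SD, n = 3). RT_TRINITY_DN2074_c0_g1 averaged 8878 ± 1820 TPM in root and 0.88 ± 0.114 in leaf (log2 fold change 12.19, SE 0.1, adjusted p = 4.1e-18), with 257.2 ± 5.42 TPM in shoot tip. RO_TRINITY_DN3981_c0_g1 averaged 2436 ± 90.2 TPM in root and 0.333 ± 0.0473 in leaf (log2 fold change 10.84, adjusted p = 3.6e-19). Both are root-only genes. LA_TRINITY_DN22130_c0_g1 reached 24070 ± 1120 TPM in leaf, 3042 ± 31.3 in leaf tip, 546.9 ± 18.8 in shoot tip and 3.49 ± 1.49 in root (root against leaf, log2 fold change -12.44, adjusted p = 3.8e-16). LA_TRINITY_DN4483_c0_g1 averaged 4053 ± 70.8 TPM in leaf, where root held 0.03, 0 and 0.06 TPM in its 3 libraries (log2 fold change -11.94, adjusted p = 1.2e-18). The share of calls higher in root was 59.1% as deposited, 48.1% after median-ratio scaling, which moved the median of all genes by -0.20, and 48.2% after quantile normalization. Under all 3 scalings 5614 genes were higher and 4954 lower in root, while a pseudocount of 5 gave 6761 genes in all and a mean of at least 5 TPM gave 7499.

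Root tip and shoot tip differed in 8181 genes, with 3769 higher in root tip and 4412 higher in shoot tip. The genes higher in root tip held 19.7% ± 0.1 of its summed TPM and 4.94% ± 0.0075 of that of shoot tip, and those higher in shoot tip 15.5% ± 0.044 there and 3.46% ± 0.018 in root tip (SD, n = 3). RO_TRINITY_DN7191_c1_g1 averaged 651.8 ± 18.9 TPM in root tip and 0.197 ± 0.0987 in shoot tip (log2 fold change 9.09, SE 0.38, adjusted p = 8.2e-11). Its root libraries held 291.15, 297.3 and 1192.57 TPM, the last in replicate 3. RT_TRINITY_DN8720_c0_g2 averaged 274 ± 4.68 TPM in root tip and 0.03 ± 0.01 in shoot tip (log2 fold change 8.06, adjusted p = 3e-11). SHA_TRINITY_DN71550_c1_g1 averaged 2814 ± 31.9 TPM in shoot tip, 2214 ± 22.6 in leaf tip, 378.7 ± 6.21 in leaf and 0.5 ± 0.161 in root tip (root tip against shoot tip, log2 fold change -10.88, adjusted p = 1.1e-13). LA_TRINITY_DN51501_c1_g1 averaged 1059 ± 7.07 TPM in shoot tip, 1003 ± 6.24 in leaf tip and 0.177 ± 0.0404 in root tip (log2 fold change -9.82, adjusted p = 1.7e-14). The share of calls higher in root tip was 46.1% as deposited and 59.3% after median-ratio scaling, which moved the median of all genes by 0.17. After quantile normalization it was 54%. Under all 3 scalings 3752 genes were higher and 3028 lower in root tip, and the total ranged from 3881 with a pseudocount of 5, where 53.9% were higher in root tip, to 13099 with one of 0.1, where 38.1% were.

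Leaf tip and shoot tip differed in 3425 genes (8.67% of those tested), the smallest number among the 6 pairs compared. In leaf tip 917 genes were higher and 2508 were lower. The higher genes held 7.63% ± 0.026 of the summed TPM in leaf tip and 2.54% ± 0.013 in shoot tip, and the lower genes 2.19% ± 0.0055 in leaf tip and 8.17% ± 0.02 in shoot tip (SD, n = 3). LA_TRINITY_DN5092_c0_g1 averaged 263.9 ± 2.49 TPM in leaf tip, 414.8 ± 5.01 in leaf and 4.42 ± 0.346 in shoot tip (leaf tip against shoot tip, log2 fold change 5.61, SE 0.053, adjusted p = 3.9e-16). LA_TRINITY_DN13843_c0_g1 averaged 35.6 ± 0.631 TPM in leaf tip and 0.0367 ± 0.0404 in shoot tip (log2 fold change 5.14, adjusted p = 4.2e-14). SHA_TRINITY_DN9182_c0_g1 averaged 658.4 ± 9.43 TPM in shoot tip and 2.25 ± 0.18 in leaf tip (log2 fold change -7.66, SE 1.2, adjusted p = 0.00013). RO_TRINITY_DN12750_c0_g1 averaged 287.2 ± 2.21 TPM in shoot tip and 1.07 ± 0.185 in leaf tip (log2 fold change -7.12, SE 1.2, adjusted p = 0.00033). In root these last genes were high in replicate 3 alone, at 474.09 and 335.59 TPM against 4.59 and 4.28 for the former and 1.8 and 2.95 for the latter, which widened the spread shared by all tissues in the fit. The number of calls was 1290 with a pseudocount of 5, 6000 with one of 0.1 and 2224 with a mean of at least 5 TPM.

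Root tip and leaf tip differed in 10555 genes, with 5363 higher in root tip and 5192 higher in leaf tip. The genes higher in root tip held 26.4% ± 0.11 of its summed TPM and 5.41% ± 0.01 of that of leaf tip, and those higher in leaf tip 22.4% ± 0.04 there and 6.56% ± 0.029 in root tip (SD, n = 3). The share higher in root tip rose from 50.8% as deposited to 64.7% after median-ratio scaling, which moved the median of all genes by 0.15. After quantile normalization it was 52.2%. Under all 3 scalings 5261 genes were higher and 3468 lower in root tip. With a pseudocount of 0.1 the balance turned, with 6982 genes higher and 8912 lower in root tip (43.9% higher of 15894). The total was 5375 with a pseudocount of 5 and 6517 with a mean of at least 5 TPM.

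Genes enriched in 1 tissue over each of the other 4 were most numerous in the mature organs. Root had 3112 enriched genes that held 28.9% ± 0.11 of its summed TPM, and leaf had 1476 that held 33.8% ± 0.48. The tips had smaller sets, with 1049 genes and 7.03% ± 0.036 in root tip, 574 genes and 2.63% ± 0.012 in shoot tip, and 233 genes and 0.78% ± 0.0024 in leaf tip (SD, n = 3 each). Identifiers with the tissue's own prefix made up 71% of the root set and 53.3% of the leaf set. They made up 63.9% in root tip, 66.1% in leaf tip and 81.2% in shoot tip. How far the set sizes depend on these prefixes was not tested. A tip also had to exceed the other tips, of which leaf tip and shoot tip were similar (r = 0.95). Of the root enriched genes 906 were root-only genes, which were selected as low in all other tissues, and 2206 were found without these. RO_TRINITY_DN2321_c0_g1, a root-only gene, averaged 14360 ± 3490 TPM in root, where replicate 3 held 18384.67 TPM and the others 12368.23 and 12319.71, and 41.9 ± 4.61 TPM in leaf as the next tissue on the fitted scale (log2 fold change 8.37, adjusted p = 9.4e-13). RT_TRINITY_DN1216_c0_g1 averaged 472.2 ± 2.3 TPM in root tip and 1.44 ± 0.0404 in shoot tip (log2 fold change 7.6, adjusted p = 1.3e-10). LA_TRINITY_DN4681_c0_g1 averaged 46.8 ± 1.03 TPM in leaf tip and 2.2 ± 0.18 in shoot tip (log2 fold change 3.9, adjusted p = 9.1e-14). SHA_TRINITY_DN12733_c0_g1 averaged 87.9 ± 2.19 TPM in shoot tip and no more than 0.3 TPM in any root library (shoot tip against root, log2 fold change 6.35, adjusted p = 6.2e-16). The leaf gene chosen by the rule was LE_TRINITY_DN3074_c0_g1, with 2587 ± 15.5 TPM in leaf and 0.847 ± 0.673 in shoot tip (log2 fold change 10.53, adjusted p = 1.7e-14). With a pseudocount of 5 the root tip, root, leaf tip and shoot tip sets held 589, 1724, 94 and 157 genes, and after median-ratio scaling the leaf tip and leaf sets held 148 and 2534.

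**Figure D5:**
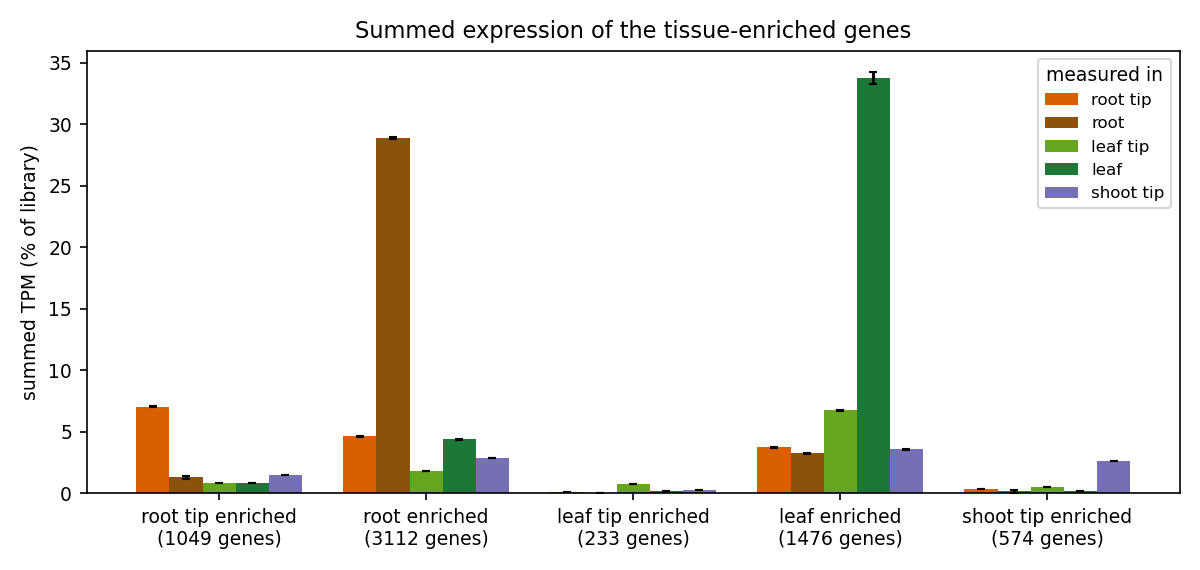
Summed TPM of each tissue's enriched genes as percent of the library total (y axis) for the 5 sets of genes (x axis), in each of the 5 tissues (bar colour); bars are means of 3 libraries and error bars are SD. Leaf enriched genes held 33.8% in leaf and 6.74% in leaf tip, and root enriched genes 28.9% in root and 4.62% in root tip.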

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

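The splits of the libraries reported here were planned before the data were examined. A total of 15125 genes had a tip effect that differed between root and leaf in the interaction contrast, which is why the result is listed here. Of 100 splits of the root tip, root, leaf tip and leaf libraries into groups of the same sizes, the real one included, 1 gave as many genes. The highest of the others gave 13051. These splits mix libraries of different tissues within groups, so they do not keep a tip effect that is equal in both organs. They therefore cannot decide whether the tip effect differs between root and leaf beyond chance.

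Among these genes 765 were also called in opposite directions in the 2 tips. Of all tested genes, 509 were called higher in root tip and lower in leaf tip, and 256 the reverse. Independent lists of the same sizes would share 830 and 1304.8 genes, so opposite calls were rarer than under independence.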

How the results depend on the processing

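Averaging root replicates 1 and 2 and leaving out root-only genes were chosen after the data were seen, and the other alternatives before. Over 15 counts of calls, 321 values under alternatives were computed. Of these 286 lay within 1.5 times the reported count and 35 did not. Many of the values left out a single library. The counts sum both directions, so they do not show a change of balance. Leaf tip against leaf lay within this range under both scalings, though its higher calls went from 9982 to 4840 after median-ratio scaling and to 6052 after quantile normalization. For the 25 named log2 fold changes, all 461 values under alternatives kept their direction and stayed past the threshold. No count, summed over both directions where there are 2, moved by over 1.5 times with array quality weights, without the intensity trend, with quantile normalization or without root-only genes, which were run for all 15. The same held where the others were run: each library left out in turn for the counts that use its tissue, only the tissues compared for the pairwise, shared tip and interaction counts, and root replicates 1 and 2 averaged for the counts that use root. The planned gene list tests and their alternatives were not run, because no identifier was paired with a name. The cause of the changes below was not tested, except that a higher pseudocount shrinks the fold changes of low genes and that the filters change how many genes are tested. The unknown depth leaves the precision of low TPM values unknown.

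With a pseudocount of 5 the counts were 6644 for root tip against root, 7737 for leaf tip against leaf, 6761 for root against leaf, 3881 for root tip against shoot tip, 1290 for leaf tip against shoot tip, 5375 for root tip against leaf tip, 7227 for the interaction, and 1923 higher and 777 lower in both tips. The enriched sets then held 589 genes in root tip, 1724 in root, 94 in leaf tip and 157 in shoot tip. With a pseudocount of 0.1 there were 13099 genes for root tip against shoot tip, 6000 for leaf tip against shoot tip, 15894 for root tip against leaf tip, 2486 lower in both tips and 399 enriched in leaf tip. Without a filter 66536 genes passed the F test. With a mean of at least 5 TPM the F test gave 21111 genes, root tip against root 7972, root against leaf 7499, root tip against shoot tip 4750, leaf tip against shoot tip 2224, root tip against leaf tip 6517 and the interaction 7917. The enriched sets under that filter held 568 in root tip, 1477 in root, 106 in leaf tip, 978 in leaf and 143 in shoot tip. Median-ratio scaling gave 2482 genes higher and 2433 lower in both tips, 148 enriched in leaf tip and 2534 enriched in leaf.

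Fits with the replicate block called 12576 genes for root tip against root, 8178 for root tip against shoot tip, 3430 for leaf tip against shoot tip and 10555 for root tip against leaf tip. Libraries with the same number did not deviate together, with correlations from -0.015 to 0.024, and 4 of 12 correlated best with their own number. No paired analysis was possible for comparisons with leaf because the numbers of its columns were not tied to single samples by the labels.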

Other observations

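The set of genes shared by the 3 tips, the root-only genes and the tests on the root libraries were chosen after the values were seen, while the splits of the libraries and the test of root tissue in the shoot tip pieces were planned before.

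In each of root tip, leaf tip and shoot tip, 2795 genes were called higher than in both root and leaf. The 6 comparisons behind this count share the root and leaf libraries. In 10 simulated draws with unchanged tips at most 1 gene met the rule. The fitted spread was their only noise and the rule needs a 2-fold difference in all 6 comparisons, so few genes could meet it. The draws held no shift from scaling and give the count no support. Independent lists of 4717, 6881 and 6892 genes for the 3 tips would share 143.4. Part of the excess over independent lists may come from the shared libraries. The genes held, by their selection, more in the tips: 14.7% ± 0.02 of the summed TPM in root tip, 21% ± 0.019 in leaf tip and 20.9% ± 0.076 in shoot tip, against 3.86% ± 0.053 in root and 3.93% ± 0.045 in leaf (SD, n = 3). A smaller set of 655 genes was lower in each tip than in both organs, with 8.36% ± 0.29 of the summed TPM in root and 6.09% ± 0.0038 in leaf and 0.727% ± 0.003 or less in the tips. Simulated draws with unchanged tips gave at most 1 such gene, with the same limit, and independent lists would share 3. Without root replicate 3 the sets held 2759 and 672 genes, of which 2691 and 635 were in the original sets. Median-ratio scaling gave 1770 and 1124 genes, of which 1770 and 655 were in the original sets. Quantile normalization gave 1821 and 1064 genes, of which 1809 and 653 were in the original sets, and a pseudocount of 5 gave 1364 and 321.

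The second-highest tissue of the enriched genes differed between tissues. Of the leaf tip enriched genes, 67.4% had shoot tip as their second tissue and 24% had leaf. Root enriched genes had root tip as the second tissue in 54.4% of cases, and leaf enriched genes had leaf tip in 39% and root in 28.6%. For root tip enriched genes it was shoot tip in 41.4% and root in 40.6%. For the shoot tip enriched genes the second tissue was root in 38.7% and leaf tip in 36.1%. The order turned to 36.1% for root and 36.9% for leaf tip without root replicate 3, and the summed TPM of these genes in root was 0.155% ± 0.12 (SD, n = 3). With root-only genes left out, 88 genes at 10 TPM or more in root were raised over 4-fold in root replicate 3. Their highest other tissue was root tip for 34 genes, shoot tip for 34, leaf for 15 and leaf tip for 5. Among all 13321 genes compared it was root tip for 39.2%, leaf tip for 23.5%, leaf for 22.8% and shoot tip for 14.6%.

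Root-only genes at 1 to 10 TPM varied between root libraries more than other genes at that level. The interquartile width of their log2 ratio between root replicate 3 and the other root libraries was 5.31 times that of other genes, while between replicates 1 and 2 it was 0.351 against 0.388. Of them 22.8% were more than 2-fold higher in replicate 3, against 5.23% of other genes at that level, and 482 of 2747 were listed at 0 in both other root libraries. These values argue against a lower depth of replicate 3 as the whole explanation, but do not exclude it. The genes were chosen on a root mean that includes replicate 3, the depth is unknown, and the depth test was written after the values were seen. Reads from other organisms living on or in the roots remain open, but the wide ratio had been seen before the test for such reads was written and gives the explanation no support. Differences between the plants sampled also remain open and were not tested, and without sequences the origin of these genes was not examined.

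Root replicate 3 stood apart from the other root libraries, with an array weight of 0.0764 against 0.756 to 1.73 for the other 14 libraries. Shoot tip tissue in that library is excluded as the whole source: 22 of the raised genes, those highest in shoot tip with at least 20 TPM there, would need a median share of 67.9%, while 707 genes abundant in shoot tip and scarce in the other root libraries reached a median of 0.359% of their shoot tip level, with an upper quartile of 1.04%. Root tip tissue is excluded in the same way, with a needed median share of 133% over the 21 raised genes chosen likewise and a median of 0.671% over 292 genes. A difference in the plants or in the part of the root taken may underlie the pattern, which was not tested.

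Genes of the root tip were also present in shoot tip at low levels. A hypothesis was that pieces of root within the shoot tip samples brought these transcripts at a single share. Over 411 genes with at least 20 TPM in root tip and under 2% of that in leaf tip, the ratio of shoot tip to root tip had a median of 4.17%, with quartiles of 1.33% and 10.6%. The interquartile width was 2.86 on the log2 scale, above the limit of 1 that had been set beforehand for a single share. This argues against such a mixture as the whole explanation. The spread that low shoot tip values add was not estimated, so the mixture is not excluded. Roots at another stage within the shoot tip pieces, and expression of these genes in the shoot tip itself, remain open and were not tested.

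Splits of the libraries into groups of the same sizes, 100 of them with the real one, were used to ask whether chance gives as many genes. All 15 libraries were split for the F test and the enriched genes. For genes higher or lower in both tips only the root tip, root, leaf tip and leaf libraries were split. For the 37754 genes of the F test 1 split gave as many, and the highest other gave 17473. For genes higher in both tips 1 split reached 3993, with 1385 as the highest other. The same count was 1 for root enriched genes (3112, highest other 78), leaf tip enriched genes (233, highest other 0) and leaf enriched genes (1476, highest other 406). It was 2 for genes lower in both tips (1572, highest other 2461), root tip enriched genes (1049, highest other 1513) and shoot tip enriched genes (574, highest other 1578). For each of these counts the share of splits with as many genes was under 0.05. The splits mix tissues, so this speaks only against an absence of tissue differences among these libraries. It cannot exclude chance differences between the plants sampled, since no label says that replicates came from separate plants. For 3 counts 1 other split gave more genes than the real one, and the cause was not tested. For each of the 6 pairwise comparisons the 6 libraries make 10 splits, too few for a share under 0.05. Of those 10 splits 1 reached the real count, which was 12574 for root tip against root, 14404 for leaf tip against leaf, 12112 for root against leaf, 8181 for root tip against shoot tip, 3425 for leaf tip against shoot tip and 10555 for root tip against leaf tip, and the highest other was 0 in each.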
